A study of Mus musculus with 8 samples.

How the data were processed

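RNA was measured in the left ventricle of 8 mice, 4 wild type and 4 with an Nppb deletion, described in the labels as littermates of the FVB strain. Per the labels' protocols, 900 ng of total RNA per sample went into a stranded total RNA library kit, and 125 bp paired-end reads were sequenced. Groups and replicate numbers were taken from the sample titles and genotype labels. The labels do not say what the replicate numbers stand for. The p-values measure the spread between these 8 animals.

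The authors deposited a table of normalized counts per gene, a signal that is never negative, with 1 column per sample. Per the submitters' processing notes, STAR, DESeq2 and the genome build mm10 were used, with no version. The annotation, the read counter and its handling of strand and of reads with several alignments are not given in the sources used here. The values of each sample were whole multiples of that sample's smallest value above 0, within 0.01 reads for 100% of values, which gave the whole reads and the size factor of each sample. Size factors recomputed from the recovered reads were 0.973 to 0.976 times the recovered ones. The authors also deposited a table of their comparison with a log2 fold change (wild type over knockout), a p-value, an adjusted p-value and a geometric mean per group, for 29240 genes, of which 5939 carry an adjusted p-value. All per-sample columns belonged to a sample of the study.

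The files hold 41128 genes, of which 28402 had a value above 0. Symbols, coordinates, lengths and GC content came from GENCODE M21, which uses the same build as the files, and 40254 gene IDs matched. Some genes hold the same reads: Rn7s1 and Rn7s2, copies of a cytoplasmic RNA, had nearly equal counts and together took 8.47% to 10.2% of the total. Mitochondrial genes took 15.6% to 17.9%. No replicates were copies of each other, since the smallest chi-square per degree of freedom between replicates of a group was 4.87. The depth of 20284865 to 34742840 gene counts per sample limits precision chiefly for genes with few reads. The interval given for Nppb is an exact 95% Poisson interval on the knockout reads and covers counting error only, since the reads carry no molecular identifiers.

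The main test was fixed before the data were examined: limma 3.58.1 with a mean-variance trend and robust empirical Bayes moderation in R 4.3.3, on log2(normalized count + 1), for the 16590 genes with a mean normalized count of at least 10. Benjamini-Hochberg adjustment used a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. A total of 37 gene lists were fixed in the same way, 20 of pathways or gene groups and 17 of cell type markers, and the 33 lists with at least 4 tested members were tested with camera at its preset correlation of 0.01, leaving Nppb out. The lymphocyte, granulocyte, lung and thymus lists had too few tested genes. Exact two-sided permutation tests enumerate 70 assignments of 4 against 4.

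Named genes were Nppb, then up to 15 genes in each direction with the largest change among those with an adjusted p under 0.05, a mean of at least 50 and no overlap between groups, leaving out unnamed gene models. Where fewer than 10 passed in a direction, genes with the smallest p that met the conditions on mean, name and overlap were added up to 10 and are said not to pass. List members past the threshold were added, the 2 members with the smallest p for called lists with none, and 13 fixed genes of the natriuretic system and cardiac remodelling. Other genes named were chosen after their values were seen. Among them are Ppargc1a, Pdk4, Ucp3, Gm13054, Myl7, Adipoq, Mfn2, Plod1, Ddx3y, genes of the authors' deposited table and genes named only in the closing sections. Not every gene near the locus is reported here.

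Alternatives changed the pseudocount (0.5 or 5), the low-value filter (none, or a mean of at least 50), the normalization (TMM factors, quantile), the variance model (no robust moderation, sample weights), the test (edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads), the replicate number as a block, each sample left out in turn, and the list test (camera with an estimated correlation, fry). The scripts were tested on simulated counts of the same genes, with 200 genes of a mean of at least 50 changed by known folds. With so many changed genes the adjusted threshold is easier to reach than where few genes pass. With 50 genes per fold, limma recovered 22 at 1.25-fold, 46 at 1.5-fold, 50 at 2-fold and 49 at 4-fold, and made 9 calls among 16390 unchanged genes. A simulated list of 33 genes lowered by 10% had a camera p of 4.37e-11, and an unchanged list one of 0.797. The simulated genes were drawn independently, so this does not test the preset correlation. In the real data the fatty acid oxidation list had an estimated correlation of 0.248.

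Some lists below were called only in refits (camera adjusted p). Ribosomal proteins were called higher with quantile normalization (0.0335) or sample weights (0.0487), and without wild-type replicate 3 (0.0065) or knockout replicate 4 (0.0135). Interferon response was called higher without wild-type replicate 2 (0.0408), and glucocorticoid response lower without knockout replicate 4 (0.0230). In the main test the results of the other lists were as follows, as medians on the log2 scale with camera adjusted p. Ribosomal proteins had 0.03 (0.0561), calcium handling and ion channels -0.02 (0.468), glycolysis 0.01 (0.759), immediate early and heat shock genes 0.04 (0.809), the circadian clock 0.00 (0.828), glucocorticoid response -0.12 (0.284), interferon response 0.01 (0.759), unfolded protein response 0.02 (0.828), renin-angiotensin and adrenergic signalling -0.03 (0.559) and sex-linked genes 0.08 (0.759). Endocardial markers had -0.12 (0.160), erythroid -0.14 (0.160), skeletal muscle -0.18 (0.185), conduction system -0.08 (0.213), adipocyte -0.06 (0.559), epicardial -0.35 (0.590), Schwann and neuron -0.12 (0.759), valve and cartilage-like -0.27 (0.120) and atrial cardiomyocyte -0.04 (0.759).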

Results

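Left ventricles of FVB mice aged 8 to 12 weeks were compared between 4 animals that lack a working Nppb gene and 4 wild-type littermates. Nppb encodes the precursor of brain natriuretic peptide, a hormone that heart muscle releases under load, and it was disrupted by a genome-edited deletion in its exon 2. Total RNA was sequenced from each ventricle. The counts assigned to genes came to 34742840, 26574894, 20284865 and 24167894 in wild-type replicates 1 to 4, and to 32036594, 33729626, 25093170 and 23063558 in knockout replicates 1 to 4. All 8 libraries expressed genes of the Y chromosome, Ddx3y among them at 2251 to 2698 normalized counts.

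The comparison asks which ventricular transcripts differ when Nppb is lost. Nppb RNA nearly disappeared from the knockout ventricles, and Nppa, the adjacent gene for atrial natriuretic peptide, rose 9.15-fold. Clcn6, the gene next to Nppa on its other side, was 35.5% higher by estimate and did not pass the test over all genes. Fatty acid oxidation genes were lower as a list at the preset correlation, with all 33 members below 0 (adjusted p = 0.823 with an estimated correlation). No other single gene passed the test.

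Nppb (ENSMUSG00000029019) lies on the forward strand of chromosome 4 from 147985788 to 147987205 in build mm10 and has 3 exons in the annotation used here. The targeted exon 2 spans 147986296 to 147986518. Its normalized count was 2713, 1840, 2761 and 4619 in wild-type replicates 1 to 4, and 4.13, 1.54, 4.09 and 2.25 in knockout replicates 1 to 4. The means were 2983 ± 1170 (SD, n = 4) and 3.003 ± 1.31 (SD, n = 4). Nppb fell by 9.53 on the log2 scale (SE 0.33), with a limma adjusted p of 4.63e-05. In whole reads the 4 knockout samples together held 13 against 11773 in the 4 wild-type samples. The depth-adjusted level in knockouts was 0.101% of the wild-type level (95% exact Poisson interval on the knockout reads 0.0536% to 0.172%, counting error only). All 8 libraries therefore matched their genotype labels at this gene.

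Nppa (ENSMUSG00000041616) begins 14.9 kb downstream of the start of Nppb, at 148000722 to 148002079 on the same strand. Its normalized count was 346, 628, 327 and 378 in the wild-type samples and 3751, 3603, 3702 and 3797 in the knockouts. The log2 fold change was 3.19 (SE 0.21; limma adjusted p = 0.0189), and an exact two-sided permutation test gave p = 0.0286, the smallest possible with 4 samples against 4. The knockout values had an SD of 83.3 around a mean of 3713, against an SD of 140 around 420 in wild type. Leaving out any sample other than wild-type replicate 2 moved the adjusted p above the threshold, to between 0.0559 and 0.206, and over all 8 such fits the log2 fold change lay between 3.09 and 3.40. The summed count of Nppa and Nppb averaged 3403 ± 1101 in wild type and 3716 ± 83.8 in knockouts (SD, n = 4; exact permutation p = 0.486).

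**Figure D1:**
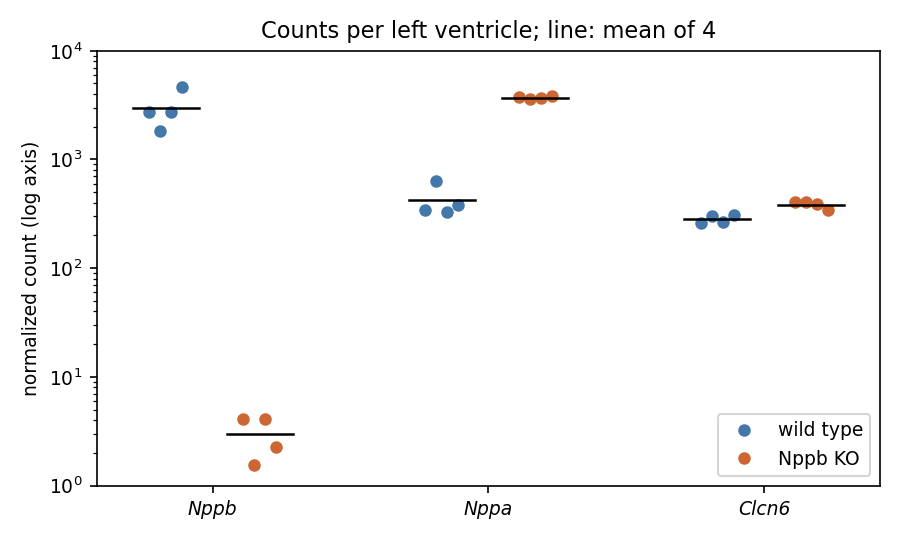
Normalized counts (log axis) of Nppb, Nppa and Clcn6 in each of the 8 left ventricles, by genotype; the line is the mean of 4. Nppb sits between 1840 and 4619 in wild type and at or below 4.13 in knockouts, Nppa between 3603 and 3797 in knockouts and at or below 628 in wild type, and Clcn6 between 345 and 407 in knockouts and between 263 and 306 in wild type.

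Of the 14 tested members of the list of genes around the locus, 1 rose adjusted over all genes and 2 adjusted over the list alone, Nppa and Clcn6. Clcn6 (ENSMUSG00000029016), which encodes a chloride and proton exchanger of late endosomes, lies on the reverse strand at 148004259 to 148038821. It measured 284 ± 22.8 in wild type and 385 ± 28.4 in knockouts (SD, n = 4), a log2 fold change of 0.44 (SE 0.08; limma adjusted p = 0.134 over all genes, 0.000339 over the list alone). DESeq2 on the recovered reads gave Clcn6 an adjusted p of 0.00396. The authors' deposited table gives Clcn6 an unadjusted p of 6.4e-07 from their comparison and no adjusted p-value. It is therefore not counted among the genes called there. A further 14 tested genes within 200 kb of Nppb had log2 fold changes from -0.10 to 0.16, none past the threshold. They include Mfn2, a mitochondrial fusion factor (-0.02), and Plod1, a collagen-modifying enzyme (0.03). Gm13054, an antisense gene overlapping Nppa and too low for the test, read 1.53 to 5.32 in wild type and 11.2 to 23.1 in knockouts. Whether the counting used strand is not given in the sources used here, so Gm13054 and Nppa reads cannot be separated with certainty. By the preset-correlation test the list was not called (camera adjusted p = 0.160; adjusted p = 0.823 with an estimated correlation), whereas fry called it (adjusted p = 0.0291). The list includes Nppa, and its median was 0.006 on the log2 scale, with 7 members above 0 and 7 below. The fry call therefore does not show a rise of the neighbouring genes in common.

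Of the 27 tested genes of natriuretic peptide and cGMP signalling, Nppa alone passed, both over all genes and adjusted over the list alone (camera adjusted p = 0.812). The receptors showed small differences that did not pass. Npr1, the guanylyl cyclase receptor for both cardiac peptides, measured 369 ± 27.4 and 368 ± 30.6 (SD, n = 4 each). Npr2, the receptor for C-type natriuretic peptide, had a log2 fold change of -0.05 (SE 0.06), and Npr3, the clearance receptor, one of 0.01 (SE 0.12). Corin, the protease that processes the atrial precursor, had a value of -0.13 (SE 0.05; limma adjusted p = 0.753). Nppc, which encodes C-type natriuretic peptide, was at or below 2.66 in every sample and was not tested.

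Among the 20 tested cardiac stress and fetal genes, again Nppa alone passed, over all genes and adjusted over the list alone (camera adjusted p = 0.468). Myh7, the slow myosin heavy chain, had a log2 fold change of -0.11 (SE 0.05), and Myh6, the adult mouse myosin, one of -0.11 (SE 0.05). These myosin genes are similar enough to share reads, so their separate values are uncertain. Ankrd1, a stretch-responsive titin partner, measured -0.06 (SE 0.10). Acta1, skeletal alpha actin, measured 10940 ± 7019 and 11240 ± 5338 (SD, n = 4 each), with wild-type replicate 2 at 21460. Within the 38 tested matrix genes 0 passed in either direction, also adjusted over the list alone (limma). Col1a1, a fibrillar collagen, had a log2 fold change of 0.03 (SE 0.21), and Postn, the matrix protein periostin, one of 0.20 (SE 0.15). The matrix list had a camera adjusted p of 0.114, and the 19 contractile genes one of 0.141, with 0 members passing. The matrix list was called higher without wild-type replicate 2, wild-type replicate 4 or knockout replicate 1 (camera adjusted p = 0.0025, 0.04999 and 0.0105). It was also called with sample weights (0.0256) and at a mean of at least 50 (0.0498), but in no other refit. The contractile list was called lower only without knockout replicate 1 (0.0105).

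Fatty acid oxidation genes were lower in the knockouts as a list. All 33 members had estimates below 0, with a median log2 fold change of -0.11 (camera adjusted p = 4.40e-11 with the preset correlation; adjusted p = 0.823 with an estimated correlation). Adjusted over all genes 0 members passed, and adjusted over the list alone 3 fell. These were Slc27a1, a fatty acid transporter (log2 fold change -0.25, SE 0.05), Cpt2, the inner-membrane carnitine transferase (-0.21, SE 0.05), and Ppargc1a, a coactivator of mitochondrial gene programs (-0.49, SE 0.12). Pdk4, which restrains glucose oxidation, and Ucp3, a mitochondrial carrier, had estimates of -0.80 and -0.81 (SE 0.26 each) and did not pass. The list mean was 0.19 lower on the log2 scale in knockouts (SD 0.07 in each group, n = 4), with no overlap of the groups (exact permutation p = 0.0286, the smallest possible).

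Transcripts encoded by the mitochondrial genome were also lower as a list, with all 13 below 0 and a median of -0.15 (camera adjusted p = 0.000408; adjusted p = 0.861 with an estimated correlation). None passed singly, also adjusted over the list alone (limma; mt-Nd4 -0.23, SE 0.07; mt-Cytb -0.15, SE 0.07). Knockout replicate 4 read 0.03 above the wild-type mean of this list, so the groups overlapped. The 54 nuclear-encoded oxidative phosphorylation genes had a median of -0.01 (camera adjusted p = 0.114). In refits they were called lower only without wild-type replicate 1 or wild-type replicate 4 (camera adjusted p = 0.0112 and 0.0471).

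Cell cycle genes were higher as a list, with 31 of 32 members above 0 and a median of 0.31 (camera adjusted p = 1.96e-07; adjusted p = 0.823 with an estimated correlation). Cenpe, a mitotic kinesin, measured 36.0 ± 4.51 and 58.5 ± 16.3, and Cdk1, the mitotic kinase, 22.4 ± 9.21 and 35.2 ± 7.84 (SD, n = 4). Replication-dependent histones had a median of 0.15 over 25 members (camera adjusted p = 0.00461; adjusted p = 0.911 with an estimated correlation), Hist1h4h and Hist1h2bc among them at 0.12 (SE 0.06) and 0.17 (SE 0.09). Macrophage markers had a median of 0.14 over 17 members (camera adjusted p = 0.00717; adjusted p = 0.861 with an estimated correlation), with Mrc1, a mannose receptor, at 0.16 (SE 0.07) and Cd68, a lysosomal glycoprotein, at 0.34 (SE 0.16). No member of these 3 lists passed over all genes or adjusted over the list alone (limma). Their means did not separate the genotypes: relative to the wild-type mean, the cell cycle list read -0.21 in knockout replicate 1 and 0.40 to 0.72 in the other knockouts, and the histone list read 0.36 in wild-type replicate 2. The histone call was lost without wild-type replicate 4, knockout replicate 2 or knockout replicate 3 (camera adjusted p = 0.233, 0.236 and 0.0559), and the macrophage call without wild-type replicate 1, wild-type replicate 3 or knockout replicate 3 (0.125, 0.0966 and 0.0746).

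**Figure D2:**
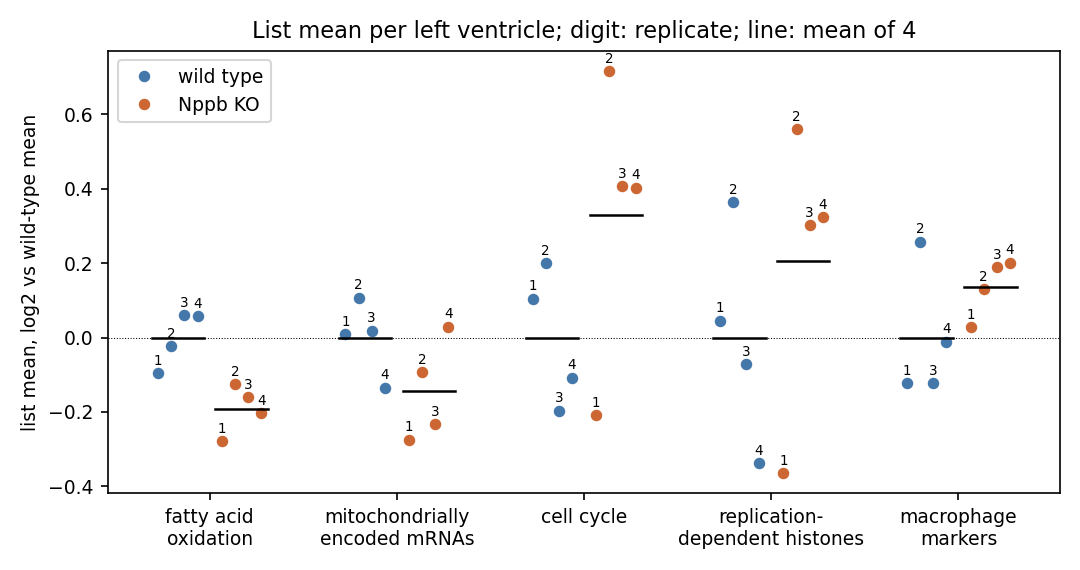
Mean of each called list per left ventricle, as the log2 difference from the wild-type mean; the digit gives the replicate and the line the mean of 4. Fatty acid oxidation separates the genotypes, with knockouts from -0.28 to -0.12 and wild type from -0.09 to 0.06, whereas the other 4 lists overlap.

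Markers of other cell types were not called in the main test. In refits erythroid markers were called lower without wild-type replicate 1 or knockout replicate 2 and with the replicate block (camera adjusted p = 0.000869, 0.0339 and 0.0331). Valve and cartilage-like markers were called lower with sample weights, the block or without knockout replicate 4 (0.0487, 0.0475 and 0.0382). Endocardial markers were called lower with sample weights or without knockout replicate 1 (0.0487 and 0.0440). Fibroblast, endothelial and smooth muscle lists had medians of -0.01, 0.01 and 0.04 (camera adjusted p = 0.759, 0.997 and 0.541). In the atrial list Nppa was the only gene to pass, over all genes and adjusted over the list alone, and the median of its 9 tested members was -0.04. Myl7, the atrial myosin light chain, stayed at or below 7.58 in every sample. Adipocyte transcripts were highest in wild-type replicate 4, where Adipoq read 19.5 against 0.77 to 6.87 elsewhere.

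The remaining genes named by the fixed rule did not pass the limma test over all genes. The lower ones with the smallest p were Npc1, a lysosomal cholesterol exporter (-0.28, SE 0.05), Tacc2, a centrosomal protein (-0.32, SE 0.05), and Wdr81, an endosomal regulator (-0.42, SE 0.07), each with a limma adjusted p of 0.0839. Kcnv2, a silent potassium channel subunit, measured -0.39, Dhrs3, a retinaldehyde reductase that lies 3.09 Mb from Nppb, -0.35, the transcription factors Nfic, Nfix and Bach1 -0.34, -0.29 and -0.26. Adjusted over the calcium handling and ion channel list alone, Kcnv2 passed (limma adjusted p = 0.00242). These lower genes, Npc1 to Bach1, passed in DESeq2 on the recovered reads (adjusted p from 0.000202 to 0.0248) and in the authors' deposited table. Higher estimates were Mir99ahg (0.27), a host transcript of microRNAs, Ppcs (0.45), an enzyme of coenzyme A synthesis, G0s2 (0.38), an inhibitor of fat breakdown, Tmx2 (0.22), and Mocs2 (0.23). Of these only Mir99ahg passed in the authors' deposited table, and none in DESeq2 on the recovered reads, which gave Ppcs no adjusted p-value. Srp54a (0.19), Srp54c (0.19) and Rpl3-ps2 (0.18) have near-identical copies, and their values are uncertain. Among them Srp54c alone passed in DESeq2 on the recovered reads (adjusted p = 0.0376).

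By limma 2 of 16590 genes passed, 1 higher and 1 lower, with 1039 at an unadjusted p under 0.05. EdgeR also called 2, whereas DESeq2 on the recovered reads called 21, 3 higher and 18 lower. The authors' deposited table lists 22 genes with an adjusted p under 0.05, of which 20 are lower in knockouts. Besides Nppb, those lower genes differ by 10.7% to 28.7% in the authors' deposited table, and 18 of the 22 are also among the 21 of DESeq2. The authors' deposited table includes Retreg1, a receptor for endoplasmic reticulum autophagy (26.9% lower), Ppargc1a (28.7% lower), Fbxo32, a muscle ubiquitin ligase (18.4% lower), and Acacb, which makes the inhibitor of fatty acid import into mitochondria (10.7% lower). In simulated counts the limma test recovered 22 of 50 genes changed by 0.32 on the log2 scale and 46 of 50 changed by 0.58, among 16590 genes. The changed genes all had a mean of at least 50, so recovery of lower genes was not tested. Genes were drawn independently, without any structure shared between samples. The simulation also changed 200 genes, which lets a larger unadjusted p pass the adjustment than where 2 genes pass. Recovery in the real data may therefore be lower.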

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

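The tests of atrial tissue and of reads running on from Nppa were chosen after the results were seen. In 6 of 90 groups of 4 samples, 1 sample stood far from the other 3, measured as its gap to the nearest divided by the range; chance gives about 1 in 20. Wild-type replicate 2 was the sample in 5 of the 6. It was highest for Acta1 (21460 against 7346 to 7589; gap 0.983 of the range), Postn (980 against 720 to 750; 0.883), Nppa (628 against 327 to 378; 0.832) and Tmx2 (1111 against 1015 to 1022; 0.927), and lowest for Bach1 (1159 against 1259 to 1279; 0.838). Knockout replicate 1 was lowest for Cd68 (85.8 against 119.6 to 120.5; 0.972). Without wild-type replicate 2 limma called 6 genes in place of 2, adding Tacc2, Npc1 and Fbxo32 (lower) and Frem2 (higher).

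Other groupings of the samples bear on the counts. Of the 35 splits of the 8 samples into 4 and 4, 3 gave at least the 2 genes of the real split, and the highest other gave 61, so chance cannot be excluded for the count. Nppb and Nppa each had an exact permutation p of 0.0286, the smallest possible and not adjusted over genes. Any gene without overlap between groups reaches it, Clcn6 and Npc1 among them, so it does not set Nppa apart. For the 5 called lists, 25 of 35 splits gave as many and the highest other gave 14. For DESeq2 on the genes tested here, 6 of 35 splits gave at least the 23 of the real split, and the highest other gave 152. The split with 61 genes places wild-type replicate 2 with knockout replicates 2 to 4. It equals the genotype split with wild-type replicate 2 and knockout replicate 1 exchanged. A sample structure other than genotype therefore cannot be told apart from a genotype effect from which these animals deviate. The 61 genes of this split include 11 histone genes, 5 members of the matrix list, 3 of the cell cycle list and 2 of the macrophage list. This split, picked for its gene count, separated the means of the 3 lists called higher, which genotype did not. The separation is partly built in, since members of these lists are among the 61 genes. Cell cycle genes read 0.20 to 0.72 in wild-type replicate 2 and knockout replicates 2 to 4, against -0.21 to 0.10 in the others. Histones read 0.30 to 0.56 against -0.36 to 0.05, and macrophage markers 0.13 to 0.26 against -0.12 to 0.03. These 3 calls therefore cannot be assigned to genotype or to such a structure.

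The higher Nppa and Clcn6 counts were set against atrial tissue in the dissection and against reads running on from Nppa. Myl7, Sln, Bmp10 and Mybphl, abundant in atria, summed to at most 11.6 normalized counts in any sample, and their highest knockout sum exceeded their lowest wild-type sum by 10.03, against a rise of 3294 for Nppa. This argues against atrial tissue as the source of Nppa. The excess of Clcn6, 101 normalized counts, came to 3.07% of the rise of Nppa. Only an excess above the rise of Nppa would have gone against run-on reads, so this ratio cannot decide the question. Transcription running past Nppa into the neighbouring, oppositely oriented Clcn6 may add to the Clcn6 count. That cannot be told apart from a rise of Clcn6 itself without the strand of the reads. A response of the locus to the loss of Nppb, or to the edited DNA, stays open and was not tested.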

How the results depend on the processing

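Nppb kept its direction and its call in all 19 alternatives, with log2 fold changes from -9.97 to -8.48. Nppa kept its direction in all 19 and its call in 11: the call was lost with a replicate block (3.19, limma adjusted p = 0.137) and without each sample except wild-type replicate 2 (leave-one-out range 3.09 to 3.40). Robust moderation gave Nppa 0.516 prior degrees of freedom against a median of 10.1 over genes, and without it the adjusted p was 6.48e-08; over all alternatives it ran from 4.39e-43 to 0.206. The count of genes, 2, became 5 with no low-value filter, 4 with sample weights and 21 with DESeq2, all 3 including Nppb and Nppa, and 1 to 6 with a sample left out (6 without wild-type replicate 2, 4 without knockout replicate 4, otherwise 1). The count of lists, 5, became 9 with sample weights, 0 with an estimated correlation, 1 with fry, and 3 to 8 with a sample left out (3 without knockout replicate 3, 8 without knockout replicate 1 or 4). Beyond the fewer samples, the cause was not tested.

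Replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.04, 0.03, -0.03 and -0.07. With the replicate block 3 genes passed, none higher. Of the 37 other named genes, 30 kept their direction throughout and 11 passed in at least 1 alternative. None of the genes that reversed passed in any fit. With quantile normalization Myh6 and Myh7 had 0 and Ankrd1 0.0069; Npr3 had -0.0258 with sample weights, -0.0102 with edgeR and -0.0045 with DESeq2; Col1a1 had -0.0088 with edgeR and -0.0069 with DESeq2. With a sample left out Npr1 ran from -0.0486 to 0.0556, Npr3 from -0.108 to 0.0815, Acta1 from -0.18 to 0.49 and Col1a1 from -0.10 to 0.15. Fatty acid oxidation, mitochondrially encoded and cell cycle lists were called in 17 of 17 refits at the preset correlation. These refits cannot test that setting, since the estimated correlations of the lists were 0.248, 0.658 and 0.459. Neither camera with an estimated correlation nor fry, used throughout in its directional form, called any of them. The mixed form of fry lets members change in either direction. It called the fatty acid oxidation list (adjusted p = 0.0223), but not the mitochondrially encoded or cell cycle lists (0.603 each). Genes of few reads, Gm13054 and Nppc among them, are limited by depth.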

Other observations

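Genes linked to fasting outside the fatty acid oxidation list had mostly lower estimates in knockout ventricles, 16 of 18. The 2 above 0 were Ddit4 (0.57, SE 0.33) and Bnip3 (0.05, SE 0.05). Klhl38, Fbxo32 and Pik3ip1 had log2 fold changes of -0.55 (SE 0.14), -0.29 (SE 0.07) and -0.34 (SE 0.09), and the autophagy gene Gabarapl1 -0.27 (SE 0.07), none past the limma threshold over all genes. Of 12 fat synthesis genes 9 had estimates above 0, with a median of 0.13 and a list mean 0.09 higher in knockouts (exact permutation p = 0.0857), with Scd2 at 0.22 (SE 0.08), Acaca at 0.15 (SE 0.07) and Insig1 at -0.27 (SE 0.08). Adjusted over the list alone only 1 passed (limma), and it was the lower gene Insig1.

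The chromosome 4 window and the explanations tested on it, and the fatty acid oxidation tests except that on GC content and length, were chosen after the results were seen. Counts over the 35 splits were planned for the window only once it had been noticed. The fasting list was also assembled after several of its members had been seen to be lower.

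Genes with low p-values were crowded around the edited locus. Within 10 Mb of Nppb, leaving out Nppb, Nppa and Clcn6, 17 of 270 tested genes had an unadjusted limma p under 0.01 (6.30%), 6 higher and 11 lower, against 1.36% of genes on other chromosomes. The 17 include Dhrs3 (-0.35), the mitochondrial carrier Slc25a34 (-0.25), the transcription factor Casz1 (-0.20) and the zinc-finger genes Zfp992 (0.26), Zfp993 (0.28) and Zfp991 (0.22). The highest count in any run of 270 consecutive genes elsewhere was 10. In this window only the real split of 35 gave as many as 17, the highest other giving 8, but the window was picked for its count in the real split. When the fullest run of 270 genes was sought anew in each split, 2 of 35 reached the 19 of the real one and the highest other held 54, so chance cannot be excluded.

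Without zinc-finger genes, gene models and pseudogenes, 6.43% of the genes in the window still had a low p against 1.54% elsewhere, which argues against reads shared within the zinc-finger cluster as the whole cause. An effect that fades with distance from the edit cannot be told apart from a broad one, with 4.08% of genes within 1 Mb and 6.79% from 1 to 10 Mb (Fisher's exact p = 0.746). A candidate explanation is a founder haplotype carried along with the edited locus, which would reach the 15 low-p genes beyond 1 Mb; no sequence variants were analysed here, so it stays open. A response of these genes to the loss of Nppb also stays open.

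The mean difference of the fatty acid oxidation list was largest in the real split (1 of 35; 0.192 on the log2 scale against 0.177 for the highest other), but this list was singled out as the strongest. Camera called it at the preset correlation in 16 of the 35 splits, the real one among them. Splits that exchange 1 animal per group keep part of the genotype contrast, so this count is not a rate of chance calls. In 5 of 35 splits the strongest list had as small a camera p. The lowest camera adjusted p elsewhere was 7.57e-21 against 4.40e-11, so chance cannot be excluded. Removing trends with GC content and gene length left a difference of -0.185 (exact permutation p = 0.0286), which argues against such a trend. Fewer cardiomyocytes in the knockout samples cannot be excluded: the contractile list mean was lower by less, -0.04, but the difference between the lists had an exact permutation p of 0.0857. Feeding state at dissection may differ between animals, and the fasting list mean was also lower (-0.194) while the fat synthesis mean was 0.09 higher, but the fasting genes were chosen knowing part of the answer and feeding is not recorded in the labels. A change of fuel use in Nppb-deficient hearts stays open as a hypothesis.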
